A study of Homo sapiens with 6 samples.

How the data were processed

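The series measured messenger RNA in 6 cultures of HepG2, a human hepatocellular carcinoma cell line, on Illumina HumanHT-12 v4 BeadChip arrays. Per the labels, 3 arrays came from cells given a small interfering RNA (siRNA) against calreticulin (CRT, gene CALR) and 3 from cells given a scramble siRNA, here called control siRNA. Cells were reverse transfected with 10 nM siRNA and harvested after 24 h, and the labels call the arrays biological replicates 1 to 3 of each group. Total RNA was amplified to biotinylated cRNA before hybridization, per the labels' protocols. The sequence of the siRNA was not given in the sources used here.

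The deposited table held, for each array and each of 47322 probes, a signal intensity and a detection p-value. GenomeStudio made them, per the submitters' processing notes, which name no version. Values below 0, down to -24.9, show that the deposited signal intensities had already been background-subtracted. Their array means, from 346.6 to 417.4, show that they had not been scaled to a common mean. The detection p-value of a probe, per the file headers, belongs to the signal beside it. A second table by the authors held the same signal intensities with each array multiplied by 1 factor, from 0.906 to 1.09, so that every array had a mean of 378.3. Its scale is linear and its probes are not centred, as the comparison of the arrays between the tables showed. The medians of its columns ran from 7.86 to 9.61. No column of values was left without a sample.

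The design fixed before the data were examined gave limma's neqc for signals that were not background-corrected, and quantile normalization with an offset for signals that were. The second case applied: 41 was added to every signal, which is 16 more than needed to make the lowest one positive, and log2 values were quantile-normalized. The offset shrinks the fold changes of dim probes. A probe was tested if its detection p was below 0.05 in at least 3 of the 6 arrays, which left 20046 probes. The annotation table paired 30113 probes with 1 gene and 8 with several, and 17201 were not listed and are unnamed here. Entrez IDs of 30074 probes matched a RefSeq gene table of assembly GRCh38.p14, and no symbol needed an update. That table was used for gene names and for the span of each gene. Its coordinates are not printed, because no genome build was given for the array's probes. Each gene was represented by its tested probe with the highest mean over all 6 arrays, chosen without the groups, which gave 11243 genes. Of the called genes, 172 had more than 1 tested probe, and in 13 of these a probe had a change of the opposite sign.

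CRT siRNA was compared with control siRNA in all 6 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariate). P-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and the words rose and fell are used for genes past it. Each gene had 4 residual degrees of freedom, to which eBayes added a prior of 8.12. The number of arrays limits the precision. Of the 34 gene lists fixed before the data were examined, the 32 with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists. The test was repeated with an estimated correlation and with fry, whose directional p asks whether a list moves on balance 1 way without comparing it with other genes. The lists covered calreticulin's known surroundings (chaperones of the endoplasmic reticulum (ER), ER stress, ER calcium, N-glycosylation, antigen presentation), liver functions, proliferation, stress and transfection responses, and markers of other cell types.

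The rule for named genes was also fixed beforehand. It took CALR, the 8 largest increases and the 8 largest decreases past the threshold whose groups did not overlap, and up to 2 members of each list that rose and up to 2 that fell, with up to 4 each way for ER chaperones. Other genes were named after their values were seen, and are marked so. The scripts were tested on simulated data with the real genes' levels and spreads and 200 changed genes. The genes of the DNA replication list were also shifted, by a log2 of -0.3. Among 11243 genes, 7 of 50 genes changed by a log2 of 0.5 were recovered, 71 of 100 at a log2 of 1 and 49 of 50 at a log2 of 2. There were 4 false calls among 131. Noise was drawn independently for each gene and array, so differences shared by many genes were not simulated. These rates may therefore not carry over to the real arrays.

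Alternatives covered the background correction, normalization, the authors' scaled values, the filter on dim probes, the probe per gene, a replicate block, array weights, the estimate of spread, the threshold, the list test and each array left out in turn. Chosen after seeing the data were neqc on the subtracted signals, a covariate for the main axis along which arrays differed within the groups, removal of each array's trend with gene span, a fit of 4 arrays, lists without their most changed member, and 6 further gene sets. The axis was taken from the residuals of these same arrays, so p-values of the fit with its covariate are too small. An exact permutation test of 3 against 3 arrays cannot give a p below 0.1.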

Results

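Gene expression was measured in HepG2 cells 24 h after transfection of an siRNA against CRT or of a scramble control siRNA, with 3 arrays in each group. Between 19108 and 21206 of the 47322 probes were detected per array, with the lowest number in control siRNA replicate 1 and the highest in control siRNA replicate 3. Correlations of normalized values lay between 0.980 and 0.993 within groups and between 0.956 and 0.987 across groups. The comparison asks how lowering the transcript of calreticulin, a calcium-binding chaperone of the ER, alters other transcripts of a liver cell line. Protein was not measured on the arrays, so the amount of calreticulin protein left at 24 h is not known.

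CALR itself fell to 22.8% of its level in the control group. The signal of its probe (ILMN_1736256), on arrays scaled to the same mean, was 1525.7 ± 152.8 (SD, n = 3) with control siRNA and 348.2 ± 29.7 (SD, n = 3) with CRT siRNA. All 3 CRT siRNA arrays lay below all 3 control arrays, as far apart as the exact permutation test allows (2-sided p = 0.1, the smallest possible). In the limma fit the log2 change was -1.95 with a standard error of 0.16 (adjusted p = 0.00011). CALR was detected in every array and was represented by 1 probe.

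Besides CALR, the transcripts that changed most with CRT siRNA belonged to none of the ER lists. MAD2L1, a spindle checkpoint gene, fell furthest, with a log2 change of -2.59 ± 0.14 (standard error, n = 3 per group). The pseudogene ZNF252P (-2.17) and NAA50 (-1.99), an N-terminal acetyltransferase, also fell further than CALR. Decreases of nearly the size of that of CALR were found for CBFB (-1.94), a partner of the RUNX transcription factors, MEST (-1.91), an imprinted gene, SNRPD2 (-1.89), a core protein of spliceosomal small nuclear ribonucleoproteins, and EIF4EBP2 (-1.77), a repressor of translation initiation. The order of these genes holds on a log2 scale whose offset shrinks the changes of dim genes. On arrays scaled to the same mean, the signal of MEST went from 299.0 to 47.7, a larger fold than that of CALR. On the same log2 scale the increases were led by CLIC3 (1.41 ± 0.20), an intracellular chloride channel protein that was detected in 1 of 3 control arrays (scaled signals 7.03 and 83.2, so that its log2 change is reduced by the offset), and by ITIH1 (1.41 ± 0.15), a secreted hepatic protein.

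The other increases of the first 8 were those of the histone gene H2BC5 (1.32), PRR15L (1.28), the pseudogene ABCC6P2 (1.27), BEX1 (1.25), CALML4 (1.19) and STMN3 (1.15). Probes of H2BC5 and ABCC6P2 may also bind transcripts of near-identical genes, so these values are uncertain. In limma, the adjusted p of the 8 largest decreases ran from 3.24e-06 for MAD2L1 to 0.00277 for SNRPD2, and that of the 8 largest increases from 0.000377 for ITIH1 to 0.0225 for H2BC5. Each of these genes was higher, or lower, in 3 of 3 CRT siRNA arrays than in every control array. H2BC5 and BEX1 lost their calls when single arrays were left out, and the other 13 genes besides CALR kept theirs without each array in turn.

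**Figure D1:**
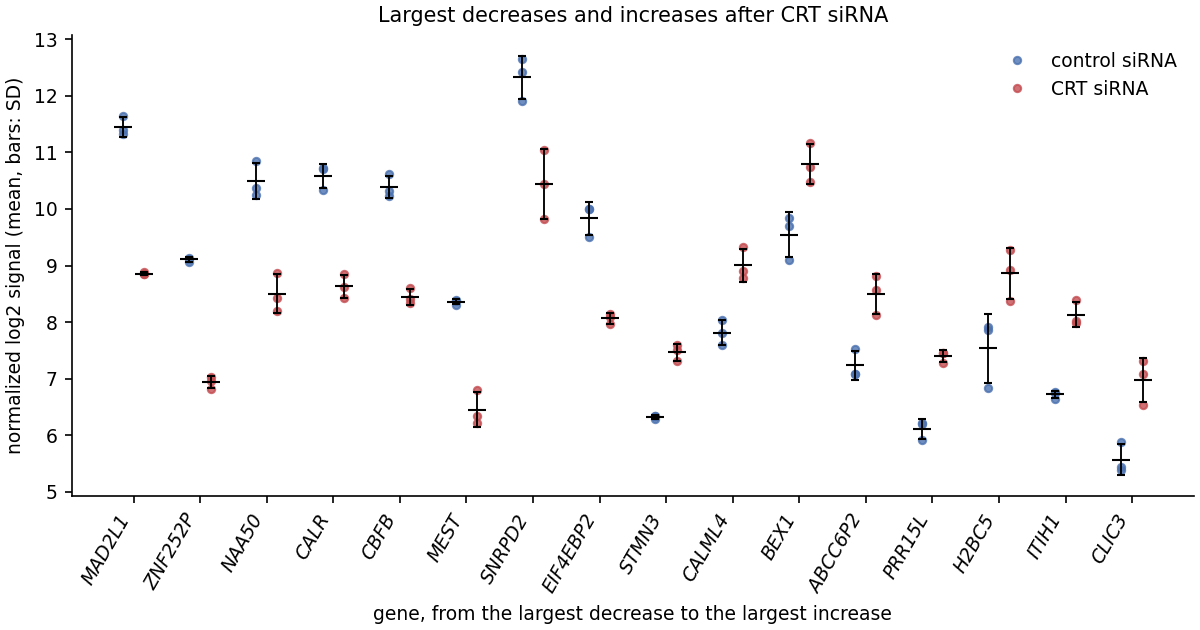
Normalized log2 signal of the 8 genes that fell most and the 8 that rose most with CRT siRNA, with a point for each array, blue for control siRNA and red for CRT siRNA. Horizontal ticks are group means and bars are SDs (n = 3), and the groups do not overlap for any of the 16 genes.

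Of the 11243 genes tested, 541 changed, 203 of them higher and 338 lower with CRT siRNA. At a fold of at least 1.5 there were 168 higher and 289 lower genes, and at a fold of at least 2 there were 19 higher and 64 lower, so 77.1% of the largest changes were decreases. The 19 higher genes became 54 without control siRNA replicate 1, 57 without CRT siRNA replicate 2 and 35 with neqc. They became 11 without control siRNA replicate 2, 9 with the 4 arrays nearest each other on the main axis of differences within groups and 7 with each array's score on that axis as a covariate. Among these settings neqc, the 4 arrays and the covariate were chosen after seeing the data. The groups did not overlap for any of the 541 genes, a property that the call itself favours. They did not overlap for 26.2% of all genes tested, where chance gives 10% on average over splits of the arrays. Genes share differences between arrays, so a single split can lie far from that average, and the excess is not a test. The number of genes depended on the arrays. In limma it was 267 without control siRNA replicate 2, 146 without control siRNA replicate 3, 196, 916 and 115 without CRT siRNA replicates 1, 2 and 3, and 207 in a fit of 4 arrays chosen after seeing the data. The balance of directions was not stable either. With array weights 2171 genes were higher and 1906 lower.

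Genes of ER protein folding changed in both directions. Of 34 tested ER chaperones, co-chaperones and disulphide isomerases, 2 rose, 1 fell and 31 did not pass the test (4 rose and 3 fell adjusted over the list alone, and such counts follow the order of their sentence throughout), and the median log2 change was 0.11. CRELD2 (0.83), an ER stress-induced secreted protein, and SDF2L1 (0.75), a co-chaperone of the ER, rose, while the disulphide isomerase TXNDC5 (-0.78) fell. The major chaperones HSPA5 (0.19, adjusted p = 0.428), HSP90B1 (-0.06, adjusted p = 0.876) and CANX (0.10, adjusted p = 0.733), named after their values were seen, did not pass in limma. The list was not shifted in camera (adjusted p = 0.199). Its medians ran from 0.05 without CRT siRNA replicate 2 to 0.18 without control siRNA replicate 2. In camera it passed in the higher direction with each array's score on the main within-group axis as a covariate (adjusted p = 0.0308). The p-values of that fit are too small, so this pass is no evidence of a shift. In the ATF6, XBP1 and ER-associated degradation list, DERL2 (0.84) and SELENOS (0.57), both components of ER-associated degradation, were the 2 of 33 tested genes that rose, none fell (4 and 2 adjusted over the list alone), and the list had a camera adjusted p of 0.329. Another tested probe of SELENOS had a change of the opposite sign. In limma the adjusted p of CRELD2, SDF2L1, TXNDC5, DERL2 and SELENOS ran from 0.0185 to 0.0462. Each of these genes lost its call when single arrays were left out.

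The list of the PERK and ATF4 branch of the ER stress response and the amino acid response shifted lower (camera adjusted p = 0.0224, but adjusted p = 0.544 with an estimated correlation), with a median of -0.17. Of its 34 tested genes, NUPR1 (0.82), a stress-induced regulator detected in 1 of 3 control arrays, rose, and DDIT4 (-0.89), an inhibitor of mTORC1, and CEBPB (-0.56), a transcription factor, fell (2 and 4 adjusted over the list alone). This shift had an adjusted p of 0.0748 without control siRNA replicate 3, 0.06 without its most changed member and 0.0969 without genes of more than 1 list. It was 0.0786 with median scaling, 0.0538 with the authors' scaled values and 0.0553 with the 4 arrays nearest each other on the within-group axis. PPP3CB (-1.01), a catalytic subunit of calcineurin, was the 1 gene that fell among 31 tested genes of ER calcium, calcium entry and calcineurin signalling, with none higher (1 and 2 adjusted over the list alone), and the list had an adjusted p of 0.45. None of 32 N-glycosylation genes and none of 17 genes of MHC class I and peptide loading passed the test, over all genes or adjusted over the list alone, and neither list was shifted (adjusted p = 0.636 and 0.116). The MHC list, with a median of 0.21, passed in the higher direction without control siRNA replicate 1 (adjusted p = 0.0411), without CRT siRNA replicate 2 (0.0359) and with a stricter detection filter (0.0414). Its median was 0.07 without control siRNA replicate 2, 0.10 without CRT siRNA replicate 1 and 0.06 with the axis as a covariate (adjusted p = 0.682). For N-glycosylation the median was -0.01 while the mean, 0.06, and the test pointed higher.

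Genes of DNA replication formed the list with the smallest p. Of 44 tested genes of G1/S and DNA replication, 6 fell, none rose and 38 did not pass (18 and 0 adjusted over the list alone), and the median was -0.35 (camera adjusted p = 4.81e-09; adjusted p = 0.188 with an estimated correlation). GINS1 (-0.98, detected in 1 of 3 CRT siRNA arrays) and MCM5 (-0.83), parts of the replicative helicase, had the largest decreases on this scale, where the offset reduces that of GINS1 (scaled signals 61.3 and 11.3). The median of 45 mitotic genes was -0.27, with a lower shift of the list (adjusted p = 3.43e-05; adjusted p = 0.316 with an estimated correlation). MAD2L1 was the only member of that list that fell, over all genes and adjusted over the list alone, and none rose. Without MAD2L1 the list kept an adjusted p of 0.00022. The growth regulators MYC (-0.88) and KLF10 (-0.65) fell among 23 immediate early genes, none rose (2 and 0 adjusted over the list alone), and the list had an adjusted p of 0.352, or 0.0156 in the lower direction with the trend with gene span removed.

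Among 24 p53 target genes TP53I3 (0.78) rose and none fell (1 and 1 adjusted over the list alone; adjusted p = 0.24). With a median of -0.16, that list passed in fry's directional test in the lower direction (adjusted p = 0.0493). CASP8 (-0.69), the initiator caspase of death receptors, and BNIP3L (-0.64), a mitophagy receptor, fell among 29 genes of the BCL2 family, caspases and death receptors, with none higher (2 and 0 adjusted over the list alone; adjusted p = 0.839). The median of that list, 0.02, was positive while its mean, -0.01, and its test pointed lower. None of 41 cytosolic ribosomal protein genes passed, also adjusted over the list alone, and the list had a median of 0.08 and an adjusted p of 0.329. The ribosomal list passed in the higher direction without control siRNA replicate 1 (adjusted p = 0.0169), with median scaling (0.048) and with the authors' scaled values (0.0225). It passed in the lower direction with the 4 arrays (median -0.12, adjusted p = 0.00529). It also did so with the axis as a covariate (median -0.07, adjusted p = 0.0258), where p-values are too small.

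There were 3 lists of liver functions that shifted higher. Of 31 plasma protein and apolipoprotein genes, ITIH1 (1.41), FETUB (0.78), LCAT (0.61) and HPX (0.55) rose and none fell (11 and 0 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 0.000173; adjusted p = 0.188 with an estimated correlation). UGT2B10 (0.73), a glucuronosyltransferase, and CYP7A1 (0.73), the rate-limiting enzyme of bile acid synthesis, rose among 26 genes of drug metabolism, bile acids and transport, none fell (2 and 0 adjusted over the list alone), and the list had a median of 0.23 (adjusted p = 0.00358; adjusted p = 0.188 with an estimated correlation; 0.056 without the filter on dim probes). SLC25A20 (0.59), the mitochondrial carnitine carrier, rose among 23 genes of fatty acid oxidation and ketogenesis, none fell (4 and 0 adjusted over the list alone), and the median was 0.19 (adjusted p = 0.00358; adjusted p = 0.188 with an estimated correlation).

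Other hepatic lists were not shifted. The coagulation factor gene F10 (0.57) rose and C4BPB (-1.05), a subunit of the complement inhibitor C4BP, fell among 34 complement and coagulation genes (5 and 2 adjusted over the list alone; adjusted p = 0.199). This list passed in the higher direction without CRT siRNA replicate 1 (adjusted p = 0.0414). It also did so with the axis as a covariate (0.0425), where p-values are too small. CREB3L3 (0.91), a liver transcription factor of the ER membrane, rose among 25 transcription factors and nuclear receptors of hepatocytes, while HNF4G (-1.03) and CEBPB fell (2 and 2 adjusted over the list alone; adjusted p = 0.639). FADS1 (-1.10), a fatty acid desaturase, and ELOVL6 (-0.58), an elongase, fell among 27 genes of fatty acid and triglyceride synthesis, none rose (3 and 0 adjusted over the list alone), and the list had an adjusted p of 0.274. SC5D (0.66), a late enzyme of the cholesterol pathway, rose among 23 genes of cholesterol synthesis, with none lower (2 and 0 adjusted over the list alone; adjusted p = 0.472).

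Transcripts of glycolysis were lower as a list. Of 17 tested genes, PFKFB4 (-0.79), PGAM1 (-0.61), PGK1 (-0.60) and PDK1 (-0.55) fell and none rose (7 and 0 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 3.27e-05; adjusted p = 0.316 with an estimated correlation). Among 19 genes of hepatic glucose handling, PKLR (0.67), the liver pyruvate kinase, rose and SLC2A1 (-1.29), the glucose transporter GLUT1, fell, also adjusted over the list alone, and the list had an adjusted p of 0.639. PIK3CB (-0.76), a catalytic subunit of phosphoinositide 3-kinase, was the 1 of 30 insulin and IGF signalling genes that fell, none rose (2 and 0 adjusted over the list alone), and the list had an adjusted p of 0.81.

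Transcripts of cytosolic heat shock proteins and co-chaperones were lower. HSPA4 (-0.78), FKBP4 (-0.68), STIP1 (-0.63) and CHORDC1 (-0.59) fell among 23 tested genes, none rose (4 and 0 adjusted over the list alone), and the median was -0.25 (adjusted p = 3.43e-05; adjusted p = 0.544 with an estimated correlation). In the list of NRF2 targets and metallothioneins the metal-binding MT1X (-1.61) and MT2A (-1.08) and the autophagy receptor SQSTM1 (-0.55) fell among 27, with none higher (4 and 0 adjusted over the list alone), and the median was -0.14 (adjusted p = 0.0258; adjusted p = 0.316 with an estimated correlation). This shift had adjusted p of 0.1, 0.0748 and 0.168 without control siRNA replicate 1, control siRNA replicate 3 and CRT siRNA replicate 2, and of 0.0719 without its most changed member. It was 0.158 with median scaling and 0.0586 with the authors' scaled values. Metallothionein transcripts are near-identical, so a probe of 1 may also read others.

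Of 22 HIF targets, SLC2A1, HIF1A (-1.02), which encodes the hypoxia-inducible factor itself, DDIT4, PFKFB4 and PDK1 fell and none rose (9 and 2 adjusted over the list alone), with a median of -0.20 (adjusted p = 0.0132; adjusted p = 0.544 with an estimated correlation). Several of these genes also stand in the glycolysis and stress lists, and without genes of more than 1 list the adjusted p was 0.822. The shift had an adjusted p of 0.0762 without control siRNA replicate 3 and of 0.06 without its most changed member.

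Nuclear-encoded respiratory chain subunits had a median of 0.28 and shifted higher (adjusted p = 0.00221; adjusted p = 0.635 with an estimated correlation), although the only member of 35 past the threshold, SDHD (-0.80), a subunit of succinate dehydrogenase, fell, also adjusted over the list alone. The adjusted p of this list was 0.25 without control siRNA replicate 2 and 0.408 with the within-group axis as a covariate, where the median was 0.09, and in the 4 arrays it was 0.864. IRF9 (0.67), a component of the interferon-activated complex ISGF3, and OAS2 (0.65, detected in 2 of 3 control arrays), a sensor of double-stranded RNA, rose among 28 interferon-stimulated genes and RNA sensors, none fell (6 and 1 adjusted over the list alone), and the median was 0.27 (adjusted p = 0.0114; adjusted p = 0.188 with an estimated correlation; 0.0871 with the axis as a covariate and 0.107 with the 4 arrays). SAA4 (0.95) and LCN2 (0.72), both secreted proteins, rose among 22 genes of inflammation and none fell, also adjusted over the list alone (adjusted p = 0.329).

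AGO2 (-0.73), the endonuclease of RNA interference, was the 1 of 12 genes of that machinery that fell, and none rose, also adjusted over the list alone (adjusted p = 0.303). Among 36 genes of integrins, focal adhesion, cytoskeleton and matrix, SPARC (0.89), a matrix glycoprotein, rose and THBS1 (-0.59), thrombospondin 1, fell, also adjusted over the list alone (adjusted p = 0.329).

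Markers of other cell types were mostly undetected in these cultures. All 15 endothelial markers on the array failed the detection filter, as did 15 of 18 fibroblast markers, and none of the 3 that were tested passed. CD68 (0.70), a lysosomal protein of macrophages, rose and the T-cell marker CD2 (-0.53) fell among 8 tested leukocyte and Kupffer cell markers, also adjusted over the list alone (adjusted p = 0.63). None of 8 markers of biliary and other epithelia passed, over all genes or adjusted over the list alone (adjusted p = 0.811).

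**Figure D2:**
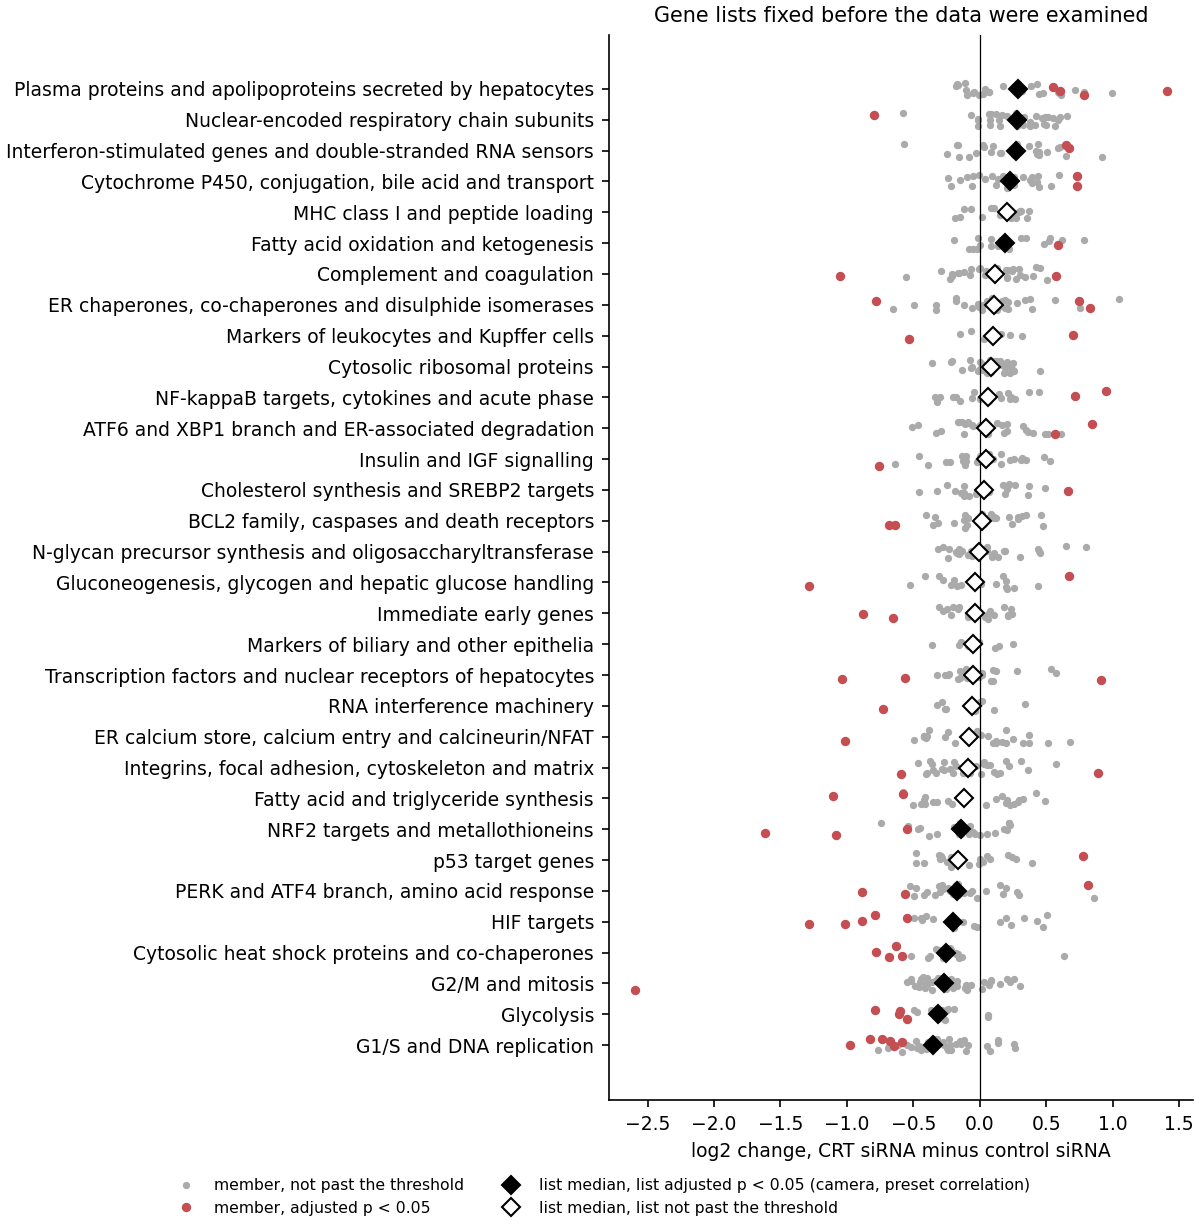
Log2 change, CRT siRNA minus control siRNA, of each tested member (points, red where limma's adjusted p is under 0.05) and the median (diamond) of each of the 32 tested lists. The 12 filled diamonds mark lists with an adjusted p under 0.05 in camera with its preset correlation, 5 with a positive and 7 with a negative median, and with an estimated correlation 0 lists passed.

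In all, 12 of 32 lists were shifted in camera with the preset correlation, 5 higher and 7 lower. With single arrays left out the medians of the 5 lists that shifted higher ran from 0.13 to 0.42 for the respiratory chain, 0.17 to 0.38 for interferon, 0.22 to 0.30 for plasma proteins, 0.18 to 0.30 for drug metabolism and bile acids and 0.15 to 0.25 for fatty acid oxidation. Those of the 7 lower lists ran from -0.45 to -0.27 for glycolysis, -0.41 to -0.30 for DNA replication, -0.32 to -0.16 for mitosis, -0.35 to -0.20 for heat shock, -0.30 to -0.14 for HIF targets, -0.24 to -0.11 for the PERK and ATF4 list and -0.18 to -0.06 for NRF2 targets and metallothioneins. With median scaling the medians were 0.46 for plasma proteins, 0.43 for the respiratory chain, 0.29 for fatty acid oxidation, -0.10 for HIF targets and -0.04 for NRF2 targets and metallothioneins. With an estimated correlation no list passed (5 at an unadjusted p under 0.05), and 7 of the 12 passed in fry's directional test (DNA replication, glycolysis, mitosis, plasma proteins, fatty acid oxidation, drug metabolism and bile acids, and interferon). Of 845 tested genes in any list, 7.10% were called, against 4.63% of the other genes. Besides ITIH1 and MAD2L1, the list members named by the rule that kept their calls without each array in turn were DDIT4, PPP3CB, SLC2A1, FADS1, C4BPB, CREB3L3, HNF4G, SPARC and HSPA4. List members named beyond the 2 largest changes each way (LCAT, HPX, PGK1, PDK1, STIP1, CHORDC1, SQSTM1, and DDIT4, PFKFB4 and PDK1 among the HIF targets) complete the counts and were named after their values were seen.

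Arrays also differed within the groups, along a main axis that held 62.5% of the variance within groups. Scores on this axis were 9.02, -29.4 and -3.27 for control siRNA replicates 1 to 3 and 24.2, -9.39 and 8.87 for CRT siRNA replicates 1 to 3. The scores of the groups overlapped (exact permutation test, 2-sided, p = 0.5), in a test that does not use the replicate numbers. Within each number the CRT siRNA array scored higher than the control siRNA array, so a difference between the groups on this axis stays open. Across genes, which are not independent replicates, a gene's weight on this axis correlated with its change with CRT siRNA (Pearson's r = 0.478). The sign of the axis was chosen so that this correlation was positive. A gene's change with CRT siRNA also correlated with its span on GRCh38.p14 (Spearman's rho = -0.237 across genes). Its weight on the within-group axis did so more strongly (Spearman's rho = -0.334). The trend with span therefore also separates arrays within the groups. With the genes cut by span into 5 groups of equal size, 74 rose and 27 fell in the group of the shortest span, with a median log2 change of 0.13, and 14 rose and 92 fell in that of the longest span, with a median of -0.05. The respiratory chain and ribosomal protein lists had the largest mean weights on this axis among the tested lists. With the axis score as a covariate the medians of the heat shock, mitosis and HIF target lists were -0.15, -0.16 and -0.10. Those of the PERK and NRF2 lists were both -0.07. All of these lists had an adjusted p under 0.05 in camera, in a fit whose p-values are too small. With the trend with gene span removed, the median of plasma proteins was 0.17 (adjusted p = 0.00223).

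**Figure D3:**
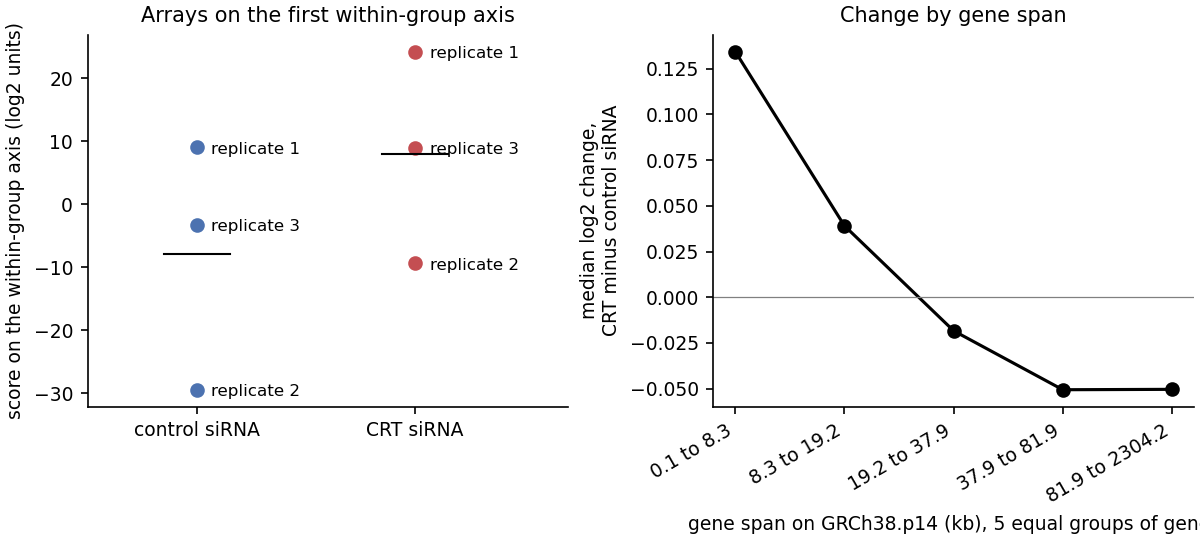
Left, the score of each array on the main within-group axis, in log2 units, with a horizontal line at each group's mean (7.89 for CRT siRNA and -7.89 for control siRNA), showing that the groups overlap. Right, the median log2 change, CRT siRNA minus control siRNA, in 5 equal groups of genes by span on GRCh38.p14 (kb), from 0.13 in the group of the shortest to -0.05 in that of the longest spans.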

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

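The histone set, the axis covariate, the removal of the span trend, the test of direct siRNA action on other transcripts, the tests of the respiratory chain, interferon, PERK and NRF2 lists alone, and the count of splits for genes were chosen only after the results were seen. Outside the genes named above, 84 of 4729 tested probes that the annotation did not pair with a single gene passed limma's threshold, 25 of them higher and 59 lower with CRT siRNA. They drew attention because a signal appeared in data that the comparison of genes does not use.

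Of the 12 shifted lists, 11 had a mean weight on the main within-group axis of the same sign as their shift. The list of NRF2 targets and metallothioneins had the opposite sign. Because the sign of the axis was chosen from the changes with CRT siRNA, matching signs were partly set in advance. A difference between arrays, such as RNA quality, is a candidate explanation, most directly for the 11. With the axis score as a covariate, in a fit whose p-values are too small, 7 of the 7 lists that fell and 3 of the 5 that rose kept an adjusted p under 0.05, and with each array's trend with gene span removed 7 of 7 and 5 of 5 did. The kept calls argue against the span trend as the whole source, but not as a part. Its removal took the median of plasma proteins from 0.29 to 0.17. Kept calls cannot decide about the axis, because the p-values of that fit are too small. With the axis covariate the median of DNA replication was -0.30, from -0.35, and those of heat shock, mitosis and HIF targets were -0.15, -0.16 and -0.10. For the respiratory chain the call ended and the median went from 0.28 to 0.0903, so this shift may come from the axis, which also stays open for interferon (median 0.139, call ended) and for the PERK and ATF4 list (-0.0674, from -0.17, call kept). For NRF2 targets and metallothioneins the values point both ways, with a mean weight that would raise the list and a kept call (adjusted p = 0.000147) but a median of -0.0681, from -0.14, so the axis stays open there too, and the loss of calreticulin stays open for these lists as an untested explanation.

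Decreases dominated the largest changes, 64 of the 83 genes that changed at least 2-fold. The within-group axis does not account for them, since their median log2 change was -1.19 with the axis as a covariate and -1.21 without. Direct action of the siRNA on transcripts that match part of its sequence, which lowers many transcripts and raises few, is a candidate explanation. The observed share of 77.1% decreases cannot decide about it. The control is also an siRNA, and transcripts that it lowers would appear as increases with CRT siRNA. Direct action also cannot be told apart here from a consequence of lowered CALR. A single siRNA label was compared with a single control, and its sequence was not used here. MAD2L1, the gene that fell most, is known from RNA interference screens as a transcript that siRNAs against other genes often lower. Across all alternative fits the share of decreases ran from 57.5% without control siRNA replicate 1 to 88.1% with the axis as a covariate.

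Histone genes were higher as a set while genes of DNA replication were lower. Of 36 tested histone genes, 6 rose and none fell, and the median log2 change was 0.39, between 0.30 and 0.51 across scalings (camera adjusted p = 2.18e-08; adjusted p = 0.218 with an estimated correlation), while the number that rose was 2 with median scaling and 3 with neqc or the smallest offset. The within-group axis as the whole source is argued against by a median of 0.32 with the axis as a covariate. The axis as a part of the source stays open, and the change of H2BC5 went from 1.32 to 0.87 in that fit. Shared probes among near-identical histone genes, which may let few transcripts appear as many, and a change in the cell cycle both stay open and were not tested. Several of the histone probes were dim, among them that of H2BC11, which rose (control mean log2 signal 5.66). In limma 0 histone genes passed without CRT siRNA replicate 1 or 3, 1 and 2 without control siRNA replicates 2 and 3, and 12 without CRT siRNA replicate 2.

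Among the 10 splits of the 6 arrays into 3 and 3, the real one gave 541 genes and the highest other split 0, so as many genes came from 1 split. For lists the real split gave 12, and again 1 split reached the real number. Every other split also gave lists, from 1 to 8, although it gave 0 genes. Camera with the preset correlation thus called lists in regrouped arrays too. With 10 splits a share under 0.05 cannot be reached. The split that set control siRNA replicate 1 and CRT siRNA replicates 1 and 3 against the rest had 2092 genes with an unadjusted p under 0.05, against 2420 for the real split, and it separates arrays by the sign of their score on the within-group axis.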

How the results depend on the processing

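CALR kept its direction and its side of the threshold under every alternative, with log2 changes from -2.18 to -1.85, and from -2.08 to -1.85 with single arrays left out. The 62 other named genes kept their direction under all alternatives and lost the threshold in 250 of 1295 comparisons. Of these genes 22 were called without each array in turn. Calls for 541 genes (203 higher, 338 lower) became 115 to 916 (25 to 448 higher, 90 to 468 lower) with single arrays left out, 142 (33 and 109) at an adjusted p under 0.01, 4077 (2171 and 1906) with array weights, whose estimation did not converge fully, and 106 higher with the authors' scaled values. Chosen after seeing the data, the axis covariate gave 932 (440 higher), with p-values that are too small because the axis comes from the same residuals, and the 4 arrays nearest each other on the axis gave 207 (60 and 147). The cause was not tested, apart from fewer arrays and a stricter threshold. Whether same-numbered arrays were paired is not known. Their deviations from the group means correlated at 0.552, 0.594 and 0.0117 for numbers 1 to 3. Arrays numbered 1 and 2 correlated best with their own number across the groups, and those numbered 3 did not, so a pairing stays open. A fit with the replicate block called 2581 genes, more of them higher (1380) than lower (1201), and the same 12 lists.

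The 12 shifted lists became 0 with an estimated correlation and 9 to 13 with single arrays left out. In 300 comparisons of these lists 262 kept the call, 37 lost it, and the respiratory chain turned lower in camera with the 4 arrays (median 0.0528). For the other lists 13 comparisons passed the threshold, 2 of them, both of ribosomal proteins, in the opposite direction. Directions in camera turned, with these medians and the cause not tested, for lists not called in the main comparison. With the 4 arrays they were ER calcium 0.131, glucose handling 0.101, hepatocyte transcription factors 0.068, adhesion 0.0709, ribosomal proteins -0.118 and biliary markers 0.0384. With the axis covariate they were glucose handling 0.0387, hepatocyte transcription factors 0.0674, adhesion -5.92e-05, ribosomal proteins -0.068 and biliary markers 0.0393. Without the most changed member, a setting also chosen later like the span trend, they were glucose handling -0.0103, apoptosis 0.0272, leukocyte markers 0.0308 and biliary markers -0.00884. Without genes of more than 1 list they were glucose handling 0.0131 and apoptosis 0.0359. Single settings turned glucose handling without the filter (0.0312), ribosomal proteins with array weights (0.0241) and without the span trend (-0.049), leukocyte markers without the span trend (0.0399) and biliary markers with median scaling (0.0616). With single arrays left out the direction also turned at times for insulin signalling (medians -0.0203 to 0.0735), glucose handling (-0.22 to 0.0677) and ribosomal proteins (-0.0221 to 0.165).

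A block for the chip could not be run because no chip was given in the sources used here, and no other probe of CALR was annotated. Signal over background limits dim genes: 4 called genes were detected in no CRT siRNA array and 6 in no control array.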

Other observations

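The gene sets described here were chosen after the values were seen, partly because members had fallen or risen, so their p-values are no independent evidence. Adjusted p-values are over the 7 tests of such sets, and those not adjusted are called unadjusted. The test of the snRNP genes was written before its result. Genes that build ribosomes were lower with CRT siRNA. Of 65 tested genes of ribosome biogenesis, 10 fell and none rose, with a median log2 change of -0.23 (camera adjusted p = 1.86e-08; adjusted p = 0.0315 with an estimated correlation). The largest decreases were those of EMG1 (-1.49), a methyltransferase of the small subunit rRNA, BOP1 (-0.89), a large subunit processing factor, and NAT10 (-0.80), an RNA acetyltransferase. The median ran from -0.27 to -0.18 across scalings, and 5, 2, 3 and 2 genes fell without control siRNA replicates 2 and 3 and CRT siRNA replicates 1 and 3. The number that fell was 5 with neqc and 6 with the smallest offset.

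Transcripts of nuclear pore proteins moved the same way. Among 29 tested nucleoporin and pore-associated genes 8 fell and none rose, led by GLE1 (-0.82), an mRNA export factor, NUP93 (-0.63) and NUP88 (-0.62), with a median of -0.29 (camera adjusted p = 7.40e-07; adjusted p = 0.168 with an estimated correlation). In limma 1, 0, 1 and 0 fell without control siRNA replicates 2 and 3 and CRT siRNA replicates 1 and 3, 5 without control siRNA replicate 1, and 4 with neqc, the smallest offset, median scaling or the authors' scaled values. Zinc finger genes of the ZNF family had 16 members that fell, such as ZNF544 (-1.21) and ZNF573 (-1.03), and 1 that rose, ZNF580 (0.67), out of 313, with a median of -0.12 (camera adjusted p = 4.82e-05; adjusted p = 0.351 with an estimated correlation). The median ran from -0.16 to -0.07 with single arrays left out and was -0.06 with the axis as a covariate, and the number that fell was 5, 8 and 2 without control siRNA replicate 3 and CRT siRNA replicates 1 and 3. Among 31 autophagy genes GABARAPL1 (0.66), GABARAPL2 (0.78) and WIPI1 (0.68) rose and SQSTM1 (-0.55) fell, and the set was not shifted (camera adjusted p = 0.279). In limma 0 autophagy genes passed without control siRNA replicate 3, CRT siRNA replicate 1 or CRT siRNA replicate 3, 1 rose and 0 fell without control siRNA replicate 2, and 2 rose and 0 fell with neqc, the smallest offset, median scaling or the authors' scaled values.

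A hypothesis was that the transcripts of spliceosomal snRNP proteins fell as a set. SNRPD2 (-1.89), SNRPB (-1.36), SNRPC (-1.09) and SNRPA (-0.65) fell and none of the 27 tested genes rose. The other 24 genes, without SNRPD2, SNRPB and SNRPC, were not lower (camera with the preset correlation, unadjusted p = 0.199, adjusted p = 0.278, in the higher direction, median 0.18). No decrease of the set beyond these 3 genes was therefore found. All 27 genes together were not shifted in the main comparison (camera with the preset correlation, adjusted p = 0.809 in the lower direction). With the axis score as a covariate the median of the 24 was 0.02 (camera with the preset correlation, unadjusted p = 0.322 in the lower direction). In that fit, whose p-values are too small, all 27 had an unadjusted camera p of 0.00846 in the lower direction (preset correlation, median -0.01). The median of the 27 was 0.17, and 0.03 and 0.04 without CRT siRNA replicate 1 and control siRNA replicate 2. The number of snRNP genes that fell was 2 without control siRNA replicate 3 and 2 without CRT siRNA replicate 3.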
